A study of Mus musculus with 24 samples.

How the data were processed

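Counts per gene were used as deposited by the authors, 1 file per library, and were whole numbers per the file headers of featureCounts 1.4.6-p5 (reads in exons summed per gene, without strand, without multi-mapping reads, mm10). Trimming with Trimmomatic and alignment with STAR were done by the submitters, per the submitters' processing notes, which give no versions. RNA was amplified with the Nugen Ovation 2 kit and made into libraries with NEBNext Ultra, per the labels. PSI values are fractions between 0 and 1 in the tables the authors deposited, made with MISO, with values kept where the credible interval was at most 0.20 wide. Per the file headers a PSI of 1 is the isoform with the exon for skipped exons and the shorter isoform for tandem UTRs, and the latter direction could not be checked in the data. P-values and false discovery rates in the authors' deposited tables come from an analysis of variance on log2(PSI/(1−PSI)) per the series notes, and served for comparison only. The same tables hold columns from crosslinking and immunoprecipitation (CLIP) of tagged CELF6, which served as a list of bound genes.

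Libraries were grouped by genotype and RNA kind as labelled, with replicates 1 to 3 from run 1 and replicates 4 and 5 from run 2. The 4 repeat runs of replicate 3 on run 2 and the WT input library labelled an outlier were left out. Libraries WT input 2 and WT input 3 were summed after the data showed them to be alike (r = 0.994 over log2 CPM, against 0.989 to 0.995 for repeat runs and 0.601 to 0.845 for the other pairs within a group). Equal numbers in input and TRAP mean the same brain by design. In a check on residual levels, KO pairs had r of −0.034 to 0.064 with 1 of 5 closest to its own number, and WT pairs −0.012 to 0.040 with 0 of 3, so the brain, as given by the number, entered as a block in alternatives only. The 18 remaining libraries were compared with the sequencing run as a covariate in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, Benjamini and Hochberg adjustment, threshold 0.05). DESeq2 1.42.0 with the same design, no expression filter, leaving out each library, and others were run as alternatives. The 4 comparisons were KO against WT in input, the same in TRAP, the difference of those 2 (interaction), and TRAP against input. The last was the mean of the differences in KO and in WT, from a fit with 1 coefficient per group. CPM printed in the text are TMM-normalized, with sample SD.

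Genes were named by rule: the 5 genes with the smallest p and at least 1 CPM in each direction for KO against WT and for the interaction, the 12 with the largest fold change past the threshold and at least 5 CPM in each direction for TRAP against input, and Celf6, Tph2, Slc6a4, Fev, Ddc and Slc18a2 in all 4. Members of lists were named from the 4 with the smallest p, and PSI events were those past the threshold and the 5 with the smallest p. Cd68 was among the smallest p in TRAP by this rule, and Ttr was named after the values were seen. Symbols were joined by name: of 24062 genes in the files, 22750 were in the gene name table and 22550 in the RefSeq table that gave positions.

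The gene lists were written before the data were examined and tested with limma 3.58.1 (camera with a correlation of 0.01, camera with the correlation estimated, and fry), with adjustment over the lists of 1 comparison. They were serotonergic neuron, dopaminergic and noradrenergic neuron, GABAergic and glycinergic neuron, glutamatergic neuron, cholinergic neuron, astrocyte, oligodendrocyte lineage, microglia and macrophage, endothelial and mural cell, ependymal and choroid plexus, fibroblast and meninges, CELF family, neuronal RNA-binding and splicing regulators, synaptic vesicle release, voltage-gated ion channels, neurotransmitter receptors, serotonin receptors, neuropeptides, axon guidance and adhesion, immediate early genes, cell cycle, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, unfolded protein and stress response, interferon and inflammation, and genes within 10 Mb of Celf6. A list of blood genes had fewer than 3 members tested, and 0 of the 13 mitochondrially encoded genes were in the files, so neither gave a result. Each member was also adjusted over its list alone. List means were compared by exact permutation over libraries, with the prior count 2 in log2 CPM.

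PSI was compared with limma on log2(PSI/(1−PSI)), with PSI held between 0.01 and 0.99, in events with a value in at least 3 libraries of each genotype, adjusted within each event class (splicing, tandem UTR) and RNA kind. The tables hold 8935 splicing events and 960 tandem UTR events, with values for 2075 to 3606 splicing events per library. Exact permutation p-values are 2-sided over all splits of the libraries with a value.

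The methods were tried on simulated data with 44 to 50 changed genes per fold and 40 to 67 changed events per shift. In input 4.08%, 52.1%, 72.3% and 80.0% of genes with 2-, 4-, 8- and 16-fold changes were found, in TRAP 10.4%, 53.2%, 77.1% and 95.5%, in the interaction 0%, 12.8%, 53.1% and 56.0%, and for TRAP against input 16.7%, 65.2%, 75.5% and 94.0%. For PSI with shifts of 1, 2 and 4 in log2 odds, 28.4%, 68.7% and 87.9% of splicing events were found in input and 17.9%, 62.7% and 90.9% in TRAP, and for tandem UTRs 39.0%, 72.5% and 87.5% in input and 26.3%, 57.9% and 92.9% in TRAP. False calls numbered 4, 4, 2 and 4 for genes in the same order, and 13 and 5 for splicing and 2 and 3 for tandem UTRs in input and TRAP, so the share of false calls among splicing events in input was above the threshold. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.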

Results

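RNA from brain tissue of mice at postnatal day 9 was compared between Celf6 knockout (KO) and wild-type (WT) animals. Celf6 encodes an RNA-binding protein of the CELF family. The tissue lay just behind the thalamus, without the cortex, and gave 2 kinds of RNA: total RNA (input) and RNA on the ribosomes of serotonin cells, pulled down by translating ribosome affinity purification (TRAP). The 19 libraries used held 3390423 to 6861963 counts each, with 13788 to 15892 of 24062 genes seen. WT input replicate 4, labelled an outlier by the submitters, held 325072 counts and was not used. The libraries labelled WT input 2 and WT input 3 differed no more than 2 sequencing runs of 1 library did (chi-square per gene 1.36, against 1.39 to 2.67 for the 4 repeat-run pairs and 26.2 to 95.4 for the 35 other pairs within a group). They were summed and are called WT input 2/3, which left n = 3 for WT input and n = 5 for each other group.

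Transcripts of the machinery that makes and moves serotonin were much more abundant in TRAP than in input. Tph2, which encodes the rate-limiting enzyme of serotonin synthesis in neurons, rose by 5.89 ± 0.36 (log2 fold change ± SE, as for all fold changes below; n = 10 TRAP and n = 8 input libraries), 59.4-fold. Gch1 and Gchfr, which make and regulate the cofactor of that enzyme, rose by 5.85 ± 0.37 and 5.53 ± 0.38. The serotonin transporter gene Slc6a4 rose by 5.37 ± 0.32 (edgeR, adjusted p = 1.26e-11), the serotonergic transcription factor gene Fev by 5.55 ± 0.38, Ddc by 4.55 ± 0.30 and the vesicular monoamine transporter gene Slc18a2 by 4.48 ± 0.35. Slc22a3, which encodes an organic cation transporter, rose by 4.64 ± 0.46. In runs 1 and 2 taken apart, the difference in mean log2 CPM was 5.94 and 5.76 for Tph2, 5.67 and 4.87 for Slc6a4, and 3.94 and 5.31 for Slc18a2. Tph2 lies on chromosome 10 at 115078641–115185022 and Slc6a4 on chromosome 11 at 76998597–77032343 (mm10).

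Cryba2 rose by 6.24 ± 0.53 and lies next to Fev on chromosome 1. 1700042O10Rik rose by 6.62 ± 0.74 but lies inside the span of Ddc on chromosome 11, so with counts made without strand its value is uncertain. Gucy2f and Hmx2 rose by 4.89 ± 0.95 and 4.82 ± 0.94. Lower in TRAP were Elf4 (−6.24 ± 0.91), Rest, which encodes a repressor of neuronal genes (−3.48 ± 0.74), the nociceptin precursor gene Pnoc (−3.20 ± 0.64), Agt (−2.90 ± 0.67) and the noradrenaline transporter gene Slc6a2 (−2.58 ± 0.55). The other 7 of the 12 lower genes that the naming rule took had log2 fold changes of −4.13 to −2.75, and each lost its call without WT input 1 or without WT input 5 (Tnfrsf1a, −4.13 ± 1.01, had an edgeR adjusted p of 0.125 without WT input 5). Celf6 itself was higher in TRAP by 1.55 ± 0.39 (edgeR, adjusted p = 0.0200), and 2.21 and 0.83 within runs 1 and 2. That call was lost without WT input 1 (adjusted p = 0.0945) and without WT input 2/3 (adjusted p = 0.0689, edgeR), and the range over all alternatives reached 0.145.

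In all, 673 of 14261 genes passed, 343 higher and 330 lower in TRAP, and 2708 had an unadjusted p below 0.05. With the brain, as given by the replicate number, as a block 413 passed, 365 of them shared, and DESeq2 called 1290, of which 666 were shared. Sex-linked genes did not match between RNA kinds for some numbers, so a number may not always stand for 1 brain. Without WT input 1 or WT input 5 the count fell to 363 and 346. With the WT libraries alone 160 genes passed and with the KO libraries alone 124.

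Of 26 serotonergic neuron genes, 16 rose and 0 fell when adjusted over all genes, and 22 rose and 1 fell when adjusted over the list alone (edgeR; median 2.45). The list was higher by camera (adjusted p = 6.08e-29, and adjusted p = 0.000756 with an estimated correlation), and its mean differed by 2.68 in run 1 and 2.42 in run 2. Of 12 serotonin receptor genes, 1 rose over all genes and 3 over the list alone, among them the autoreceptor gene Htr1a (1.395 ± 0.295; camera adjusted p = 0.0901). Cytosolic ribosomal protein genes were also higher (69 tested, 63 positive, median 0.53; Rps15 1.18 ± 0.29 and Rpl6 1.32 ± 0.35 rose, 2 over all genes and 2 over the list alone). That list passed camera at adjusted p = 1.43e-05 but had adjusted p = 0.606 with an estimated correlation and 0.200 by fry. The within-run mean over both genotypes was 0.39 in each run, but the libraries did not go 1 way. In run 2 KO TRAP 4 and 5 (3.95 and 3.97 log2 CPM) lay below KO input 4 and 5 (4.30 and 4.33). WT TRAP 4 and 5 (5.18 and 5.51) lay above WT input 5 (4.21). In run 1 KO TRAP 1 (3.81) and WT TRAP 1 (3.99) lay below KO and WT input 1 (4.25 each). TRAP libraries 2 and 3 of both genotypes (4.66 to 5.19) lay above input.

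Genes of glia were lower in TRAP. Of 18 oligodendrocyte lineage genes, 8 fell over all genes and 13 over the list alone, led by the myelin gene Mbp (−1.97 ± 0.22), Olig1 (−1.81 ± 0.22) and Olig2 (−1.80 ± 0.30). That list had median −1.22 and camera adjusted p = 4.31e-12, with adjusted p = 0.110 with an estimated correlation. Of 15 astrocyte genes, 6 fell over all genes and 9 over the list alone, among them Glul (−1.38 ± 0.20), Sox9 (−2.04 ± 0.35) and Gfap (−1.29 ± 0.25). The astrocyte median was −0.90 with camera adjusted p = 7.61e-09, and adjusted p = 0.101 with an estimated correlation. Within runs 1 and 2 the oligodendrocyte mean was −1.44 and −1.36 and the astrocyte mean −1.27 and −0.96. Microglia and macrophage genes (15 tested, median −1.01, camera adjusted p = 0.00689) had adjusted p = 0.135 with an estimated correlation, and 0 passed over all genes and 1 (P2ry12, −2.93 ± 0.89) over the list alone. Fibroblast and meninges genes (10 tested, median −1.10, camera adjusted p = 0.000944) had adjusted p = 0.135 with an estimated correlation, and 1 fell over all genes (Igf2, −2.08 ± 0.26) and 3 over the list alone. Endothelial and mural cell genes (15 tested, median −0.60, camera adjusted p = 0.0223, 0 past over all genes or over the list alone) had adjusted p = 0.266 with an estimated correlation. Without WT TRAP 2 or KO TRAP 4 the endothelial call was lost, with a highest adjusted p of 0.0765 by camera.

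Genes of other transmitter systems were lower in TRAP as well. Dopaminergic and noradrenergic neuron genes had median −1.06 (9 tested; 1 fell over all genes, 3 over the list alone; camera adjusted p = 0.000458, and adjusted p = 0.120 with an estimated correlation). GABAergic and glycinergic neuron genes had median −0.84 (11 tested; Gad2 −1.03 ± 0.24 and Slc32a1 −1.23 ± 0.37 were the 2 that fell over all genes, with 4 over the list alone; camera adjusted p = 0.000458, and adjusted p = 0.110 with an estimated correlation). Glutamatergic neuron genes had median −0.98 (9 tested; Camk2a −1.03 ± 0.20, Barhl1 −1.64 ± 0.42 and Neurod2 −1.99 ± 0.57 were the 3 that fell over all genes; 2 rose and 5 fell over the list alone; camera adjusted p = 0.0195, and adjusted p = 0.110 with an estimated correlation). Cell cycle genes had median −0.49 (26 tested, 0 past over all genes or over the list alone; camera adjusted p = 0.0195, and adjusted p = 0.135 with an estimated correlation). Immediate early genes had median −0.87 (17 tested; Egr1 −1.85 ± 0.37 was the 1 that fell over all genes and over the list alone). Their camera adjusted p of 0.0413 became an adjusted p = 0.120 with an estimated correlation, and the call was lost without any 1 of 9 libraries (WT TRAP 1, 2 and 3, KO TRAP 3, 4 and 5, KO input 2 and 4, WT input 2/3; highest adjusted p 0.0916). Taken over both genotypes, all 12 called lists kept their direction in each run, and the rotation test fry called 12 lists, 10 of them shared.

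Celf6 RNA was lower in KO than in WT TRAP, at 50.5 ± 37.5 CPM (mean ± SD, n = 5) against 140 ± 39.8 CPM (n = 5), a log2 fold change of −1.52 ± 0.38. In TRAP 4 of 5 KO libraries had less Celf6 than every WT library (exact permutation p = 0.0159 over 252 splits, smallest possible 0.00794), and KO TRAP 1, at 113 CPM, was the other. The difference in mean log2 CPM was −1.69 in each run. Adjusted over all genes Celf6 did not pass (edgeR, adjusted p = 0.9992; from 0.0323 without the expression filter to 1.00 over the alternatives), and adjusted over the 6 CELF family genes alone it did (0.00457). In input Celf6 averaged 15.5 ± 6.51 CPM in KO (n = 5) and 52.2 ± 48.2 CPM in WT (n = 3), −1.56 ± 0.66, with an exact permutation p = 0.0893 over 56 splits. The input difference rested on WT input 5 (107 CPM): without it the value was −0.44. WT input 2/3, at 15.7 CPM, lay within the range of KO input (4.90 to 22.5 CPM). WT input 5 held RNA of Xist and of Y-linked genes together. The WT level in input is thus uncertain. The input difference in mean log2 CPM was −0.35 in run 1 and −3.46 in run 2, which holds 1 WT input library. The genotype difference in TRAP less that in input was 0.38 ± 0.74. In mean log2 CPM it was −1.34 in run 1 and 1.80 in run 2. Celf6 lies on chromosome 9 at 59578337–59607292 (mm10).

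No difference between genotypes was found for serotonin genes in the serotonin-cell RNA. Tph2 in TRAP was at 1803 ± 768 CPM in KO and 1479 ± 369 CPM in WT (n = 5 each; 0.29 ± 0.31) and Slc6a4 at 2800 ± 537 and 3049 ± 1332 CPM (−0.10 ± 0.29). Fev, Ddc and Slc18a2 had log2 fold changes of 0.32 ± 0.33, −0.10 ± 0.25 and 0.31 ± 0.31 (edgeR, adjusted p = 0.9992 for each). In input the same genes had 0.17 ± 0.57 (Tph2), 0.16 ± 0.40 (Slc6a4), 0.67 ± 0.66 (Fev), −0.10 ± 0.51 (Ddc) and 0.17 ± 0.65 (Slc18a2; adjusted p = 1.00 for each, edgeR). The serotonergic neuron list had median 0.04 in TRAP (camera adjusted p = 0.726) and 0.09 in input (camera adjusted p = 0.841), with 0 genes past over all genes or over the list alone. In mean log2 CPM the sign in TRAP turned between runs 1 and 2 for Tph2 (−0.33 and 0.95), Slc6a4 (−0.31 and 0.47) and Ddc (−0.29 and 0.20). In input it turned for the same genes: Tph2 (0.70 and −0.96), Slc6a4 (−0.21 and 0.75) and Ddc (0.65 and −1.26). For Fev and Slc18a2 the sign was the same in both runs in each RNA kind.

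No gene passed between genotypes. In TRAP edgeR called 0 of 12204 genes, with 455 at an unadjusted p below 0.05 where 610 would be expected by chance, and DESeq2 called 1. In input edgeR called 0 of 13036 genes, with 376 below 0.05 where 652 would be expected, and DESeq2 called 0. Of genes simulated with a 4-fold change, 53.2% were found in TRAP and 52.1% in input, and of those with a 2-fold change 10.4% and 4.08%, so modest changes would have been missed.

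Among the genes with the smallest p, Ptgds, which encodes prostaglandin D synthase, had the same direction in both RNA kinds. In TRAP its RNA was at 50.2 ± 47.7 CPM in KO and 240 ± 128 CPM in WT (n = 5 each; −2.30 ± 0.60; exact permutation p = 0.0159), with 4 of 5 KO libraries below every WT library. In input it was at 202 ± 245 CPM in KO (n = 5) and 772 ± 174 CPM in WT (n = 3), −2.11 ± 0.57 (exact permutation p = 0.0714), and KO input 3 was the highest KO library at 637 CPM. Ptgds passed in input without KO input 3 (−3.07, edgeR, adjusted p = 0.00207) and without the expression filter (2.28e-11), and in TRAP without the filter (2.43e-07), with the other end of each range at 1.00. In mean log2 CPM Ptgds differed by −2.10 and −3.20 in input and by −1.93 and −3.73 in TRAP in runs 1 and 2. Ptgds was named for its small p in the same data, so its exact p-values are no independent evidence. By design input and TRAP come from the same brains, so the 2 RNA kinds were not taken as independent. Sex-linked genes did not match between the RNA kinds for every number. Ptgds was lower in TRAP than in input (−1.88 in mean log2 CPM), so whether its difference lies in serotonin cells was not settled. Ptgds lies on chromosome 2 at 25466712–25469749 (mm10).

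Other genes with small p in TRAP did not pass (edgeR, adjusted p = 0.9992 for each). H2-T24 had 2.38 ± 0.61, the adhesion gene Cadm1 1.25 ± 0.32, Chml 1.65 ± 0.44, Rock2, which encodes a kinase of the actin skeleton, 1.48 ± 0.41, and Cdk5r1, which encodes the activator of the neuronal kinase CDK5, 1.01 ± 0.29. Bambi had −5.21 ± 1.31, Gpn2 −2.99 ± 0.81 and the macrophage gene Cd68 −5.12 ± 1.31, with Cd68 at 0.501 ± 0.963 CPM in KO and 12.8 ± 7.65 CPM in WT (n = 5 each). Cd68 was lower in 5 of 5 KO libraries than in every WT library (exact permutation p = 0.00794, the smallest possible) and was the 1 gene called by DESeq2 (−5.31, adjusted p = 0.0193). Such separation, in either direction, was seen for 91 of 12204 genes in TRAP (0.746%), where 0.794% would be expected by chance. Cd68 was named for its small p in the same data, so its exact p is no independent evidence. In input BC004004 (1.38 ± 0.36), Zfp414 (1.38 ± 0.36), Sltm (2.13 ± 0.57), Ccdc115 (1.73 ± 0.48), Inpp5d (5.82 ± 1.70), Mpzl2 (−6.40 ± 1.61), Zfp94 (−3.30 ± 0.86), Lepre1 (−2.71 ± 0.76) and Slc16a10 (−5.08 ± 1.45) had the smallest p, and edgeR gave each an adjusted p of 1.00.

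By list, ribosomal protein genes were lower in KO than in WT TRAP, with 60 of 65 negative and median −0.47 (camera adjusted p = 3.40e-07; adjusted p = 0.801 with an estimated correlation). Rplp2 had −0.80 ± 0.38, Rps14 −0.79 ± 0.41 and Rpl8 −0.62 ± 0.32. Nuclear oxidative phosphorylation genes followed, with 58 of 70 negative and median −0.24 (camera adjusted p = 0.00689; adjusted p = 0.801 with an estimated correlation; Cyc1 −0.57 ± 0.31, Cox7b −0.56 ± 0.31). Neither difference held within both runs. The list mean of the ribosomal genes differed by 0.13 in run 1 and −1.45 in run 2, and that of the oxidative phosphorylation genes by 0.08 and −0.70. Permuted over libraries, the ribosomal mean was 4.56 ± 0.62 in KO and 5.06 ± 0.61 in WT (log2 CPM, mean ± SD, n = 5 each; exact permutation p = 0.222), and over all lists the lowest adjusted p of that test was 0.825 (exact permutation).

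Neurotransmitter receptor genes were higher in KO TRAP (31 of 45 positive, median 0.20; camera adjusted p = 0.00708; adjusted p = 0.801 with an estimated correlation), among them the muscarinic receptor gene Chrm2 (1.56 ± 0.65) and Gabrb2 (0.90 ± 0.40). Voltage-gated ion channel genes had 25 of 41 positive and median 0.16 (camera adjusted p = 0.0443; adjusted p = 0.801 with an estimated correlation), among them the potassium channel genes Kcnq5 (1.69 ± 0.57) and Kcnd3 (1.10 ± 0.37). Dopaminergic and noradrenergic neuron genes were lower (7 of 8 negative, median −0.82; camera adjusted p = 0.0147; adjusted p = 0.801 with an estimated correlation; Slc6a2 −1.36 ± 1.01, Aldh1a1 −1.10 ± 0.90). Microglia and macrophage genes were lower too (5 of 7 negative, median −0.77; camera adjusted p = 0.0443; adjusted p = 0.801 with an estimated correlation), with Csf1r at −0.86 ± 0.82 and Cd68 past when adjusted over the list alone (0.00711). Within runs 1 and 2 the list means differed by 0.54 and −0.09 (receptors), 0.13 and 0.21 (channels), −0.71 and −1.43 (dopaminergic and noradrenergic), and −0.24 and −2.36 (microglia), so the receptor difference did not hold in run 2. In these 6 lists 0 genes passed over all genes and only Cd68 over its list alone, and fry called 0 lists by direction and 1 without regard to direction (microglia, adjusted p = 0.00118). The microglia list and the dopaminergic and noradrenergic list were also lower in TRAP than in input. RNA of other cells varied between TRAP libraries: the oligodendrocyte lineage mean was 4.29 in WT TRAP 2 and 6.97 in WT TRAP 4 (log2 CPM). The oligodendrocyte list itself did not pass between genotypes in TRAP (median −0.04, camera adjusted p = 0.617). Whether the microglia and dopaminergic differences lie in serotonin cells was therefore not settled.

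The ribosomal call held without any 1 TRAP library (highest adjusted p 0.00993, camera). All other lists were lost without WT TRAP 5, which left 1 list, and leaving out KO TRAP 5, 4 and 3 left 3, 3 and 4 of the 6. Receptors were also lost without WT TRAP 2 and KO TRAP 3 (highest adjusted p 0.185), channels without WT TRAP 2, KO TRAP 3 and 5 (0.318), and oxidative phosphorylation without KO TRAP 4 and 5 (0.531, camera). Dopaminergic and noradrenergic genes were lost without WT TRAP 1, KO TRAP 2 and 4 (highest adjusted p 0.101), and microglia genes without WT TRAP 1 and 4, KO TRAP 4 and 5 (0.216, camera). In input 0 of 26 lists passed (camera, lowest adjusted p = 0.302, for ependymal and choroid plexus genes, median −1.17, and immediate early genes, median −0.26), and without KO input 4 the count was 1.

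The genotype difference in TRAP less that in input passed for 0 of 14261 genes (edgeR; 554 at an unadjusted p below 0.05, 713 expected by chance; DESeq2 3). The genes with the smallest p were Nron (13.55 ± 3.32), Ica1 (2.20 ± 0.56), Sh2d4b (9.82 ± 2.55), Tha1 (7.89 ± 2.12), Zfp597 (2.44 ± 0.69), Mfsd11 (−4.39 ± 0.98), Inpp5d (−9.19 ± 2.25), Commd7 (−2.26 ± 0.57), Gsg1l (−1.84 ± 0.47) and Adh7 (−12.40 ± 3.07), each with an edgeR adjusted p of 1.00. DESeq2 called Mfsd11 (−4.40, adjusted p = 0.000189) and Inpp5d (−9.29, adjusted p = 0.00641). For the serotonin genes the values were 0.12 ± 0.54 (Tph2), −0.38 ± 0.48 (Slc6a4), −0.39 ± 0.58 (Fev), 0.03 ± 0.48 (Ddc) and 0.28 ± 0.56 (Slc18a2). In mean log2 CPM the sign turned between runs 1 and 2 for Tph2 (−1.04 and 1.95), Ddc (−0.95 and 1.503), Fev (−0.78 and 0.48) and Slc18a2 (−0.0138 and 0.69), and not for Slc6a4 (−0.11 and −0.24). Of genes simulated with a 4-fold difference 12.8% were found here.

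By list, ribosomal protein genes (median −0.50, camera adjusted p = 0.000467; adjusted p = 0.902 with an estimated correlation) and oxidative phosphorylation genes (median −0.28, camera adjusted p = 0.00654; adjusted p = 0.902 with an estimated correlation) were lower in KO relative to WT in TRAP than in input. Dopaminergic and noradrenergic genes (median −0.60) and microglia genes (median −1.10) were lower as well, and channel genes (median 0.37) were higher, each with a camera adjusted p = 0.0114 and an adjusted p = 0.902 with an estimated correlation. Of these 5 lists 0 genes passed over all genes or over the list alone. Within runs 1 and 2 the ribosomal mean differed by 0.23 and −1.49 and the oxidative phosphorylation mean by 0.04 and −0.72, so neither held in run 1, while dopaminergic (−0.46, −2.56), microglia (−0.82, −1.74) and channel means (0.13, 0.62) kept their direction. Without KO TRAP 4 the count was 0 lists (ribosomal adjusted p 0.0512, camera), and without KO TRAP 5 or WT input 5 it was 3 for each. Besides these, oxidative phosphorylation was lost without WT input 2/3 or KO input 5 (highest adjusted p 0.755), microglia without WT input 1 or WT TRAP 4 (0.145), and channels without KO input 1 or 4 (0.0880, camera), while the highest for dopaminergic genes was 0.170.

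Nmnat2, which encodes an enzyme that makes NAD and keeps axons alive, differed between KO and WT TRAP in the use of its 2 3′ UTR forms. Its percent spliced in (PSI) is the share of the shorter UTR per the file headers, a direction that the data here could not check, and if turned the shift is toward the longer UTR. The PSI was 0.980 ± 0.00262 in KO (mean ± SD, n = 4) and 0.495 ± 0.129 in WT (n = 3), a difference of 5.63 ± 0.39 in log2 odds (limma, adjusted p = 0.00167; exact permutation p = 0.0286 over 35 splits, the smallest possible). In run 1 the means were 0.978 in KO (n = 2) and 0.569 in WT (n = 2), and in run 2 they were 0.981 (n = 2) and 0.347 (n = 1). Polr2m, which encodes a protein bound to RNA polymerase II, had a higher PSI in KO as well, at 0.985 ± 0.00435 in KO (n = 3) and 0.895 ± 0.0453 in WT (n = 5; 2.92 ± 0.44, limma, adjusted p = 0.0399; exact permutation p = 0.0179). Both events were picked for their small p in the same libraries, so their exact p-values are no independent evidence. The long and short Nmnat2 UTRs span chromosome 1 at 153115670–153119265 and 153115670–153116070, and the Polr2m pair ends at 71479395 on chromosome 9 (mm10). In input Nmnat2 had a value in 2 WT libraries and was not tested (KO 0.779 ± 0.243, n = 5; WT 0.534 ± 0.0363, n = 2). Polr2m was not tested in input either, and its mean there was not higher in KO (KO 0.962 ± 0.0414, n = 4; WT 0.968 ± 0.0159, n = 2).

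The skipped exon of Zhx1 on chromosome 15 (58052224–58055082, mm10) was included more often in KO TRAP. Its PSI, the share with the exon, was 0.9904 ± 0.00262 in KO and 0.968 ± 0.00860 in WT (n = 5 each; 1.57 ± 0.20, limma, adjusted p = 0.0384; exact permutation p = 0.00794). Zhx1 too was picked for its small p in the same libraries, so its exact p is no independent evidence. In runs 1 and 2 the Zhx1 means were 0.989 against 0.965 and 0.993 against 0.972, and those of Polr2m 0.988 against 0.907 and 0.981 against 0.877. In input the Zhx1 exon was not tested, and its mean there was not higher in KO (KO 0.977 ± 0.0109, n = 4; WT 0.986, n = 1). The Zhx1 event is shared with the readthrough gene 9130401M01Rik, so which gene it belongs to is uncertain. Zhx1 was lost with wider bounds on PSI (adjusted p = 0.244), with the run as a covariate (0.0506) and without any 1 of KO TRAP 1 to 5 and WT TRAP 2, 3 and 5 (highest 0.156, limma), and its lowest adjusted p was 0.00944, where a value was needed in every library. Polr2m was lost with the run as a covariate (adjusted p = 0.0743) and without any 1 of WT TRAP 1 to 4 (highest 0.152, limma; lowest over the alternatives 0.0347). Polr2m could not be tested without KO TRAP 1, 3 or 4, or where a value was needed in every library. Its FDR in the authors' deposited analysis of variance was 0.103. Nmnat2 passed with the run as a covariate (adjusted p = 0.00699, limma) and without any 1 of the 4 KO TRAP libraries in which it had a value (0.0126 to 0.0152). Nmnat2 could not be tested without WT TRAP 1, 2 or 4, or where a value was needed in every library. With KO and WT numbers as a block the calls of Nmnat2, Polr2m and Zhx1 were all lost, though equal numbers were not taken as pairs.

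Among events that did not pass in TRAP, the mutually exclusive exons of the synaptic gene Snap25 had a mean PSI of 0.888 ± 0.0163 in KO and 0.822 ± 0.0157 in WT (n = 5 each; 0.78 ± 0.15, limma, adjusted p = 0.164). The retained intron of Fam70a was at 0.0188 ± 0.00294 against 0.00816 ± 0.00300 (n = 5 each), the exon of Pfdn5 at 0.938 ± 0.0192 (n = 5) against 0.984 ± 0.00261 (n = 4; adjusted p = 0.0678 for both, limma) and that of Wac at 0.983 ± 0.00525 against 0.937 ± 0.0157 (n = 4 each). Fam70a passed where a value was needed in every library (adjusted p = 0.00944, limma; up to 0.823 in other settings) and Pfdn5 without KO TRAP 2 (adjusted p = 0.0268; up to 0.284). The UTR of Arl5a was at 0.720 ± 0.0769 against 0.364 ± 0.0806 and that of Ubn1 at 0.977 ± 0.00356 against 0.937 ± 0.0160 (n = 3 each), and that of Mapk1ip1l at 0.164 ± 0.0444 against 0.277 ± 0.0583 (n = 5 each). In input (n = 5 KO and n = 3 WT) the same was so for Phb2 (0.0130 against 0.0469), Sh3glb2 (0.0450 against 0.0144), Uqcrc2 (0.0223 against 0.0553), Max (0.952 against 0.857) and A730017C20Rik (0.0544 against 0.125, n = 3 each; limma, adjusted p = 0.973 for each). It was so too for the UTRs of Mnt (0.976 against 0.949), Marchf6 (0.188 against 0.0741), Tomm40l (0.0981 against 0.0166) and Rab10 (0.580 against 0.946, n = 3 each). The UTR of Eno2 was at 0.240 ± 0.0282 in KO and 0.139 ± 0.0297 in WT input (limma, adjusted p = 0.204) and at 0.180 ± 0.0382 and 0.267 ± 0.0458 in TRAP.

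In TRAP 1 of 1861 splicing events and 2 of 340 tandem UTR events passed (112 and 18 at an unadjusted p below 0.05, where 93.1 and 17.0 would be expected). In input 0 of 1154 and 0 of 242 passed (limma; 38 and 16 at an unadjusted p below 0.05, where 57.7 and 12.1 would be expected). The authors' deposited table has 1 splicing event (Surf2, FDR 0.0368) and 1 tandem UTR event (Nmnat2, FDR 0.00956) below 0.05 in TRAP and 0 in input.

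**Figure D1:**
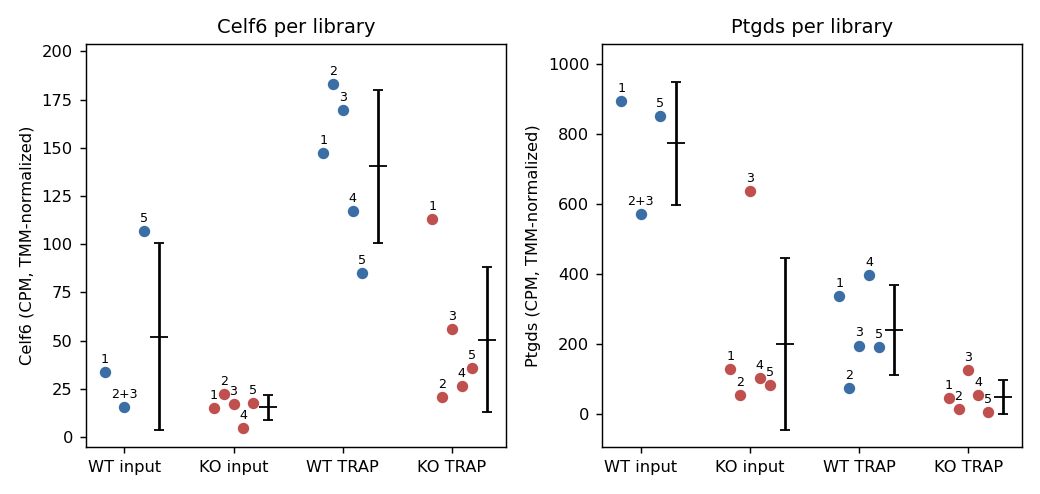
Celf6 and Ptgds in each library (CPM), by genotype, for input and TRAP, with mean and SD.

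**Figure D2:**
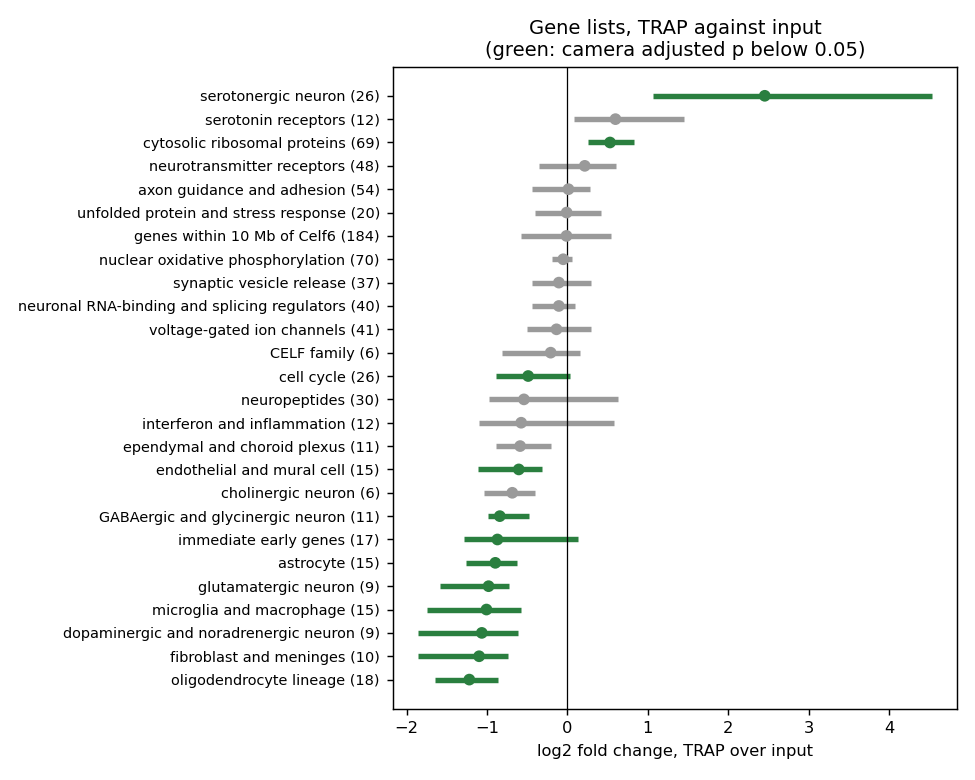
Median log2 fold change, with quartiles, of each gene list between TRAP and input; green marks lists past camera at adjusted p below 0.05.

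**Figure D3:**
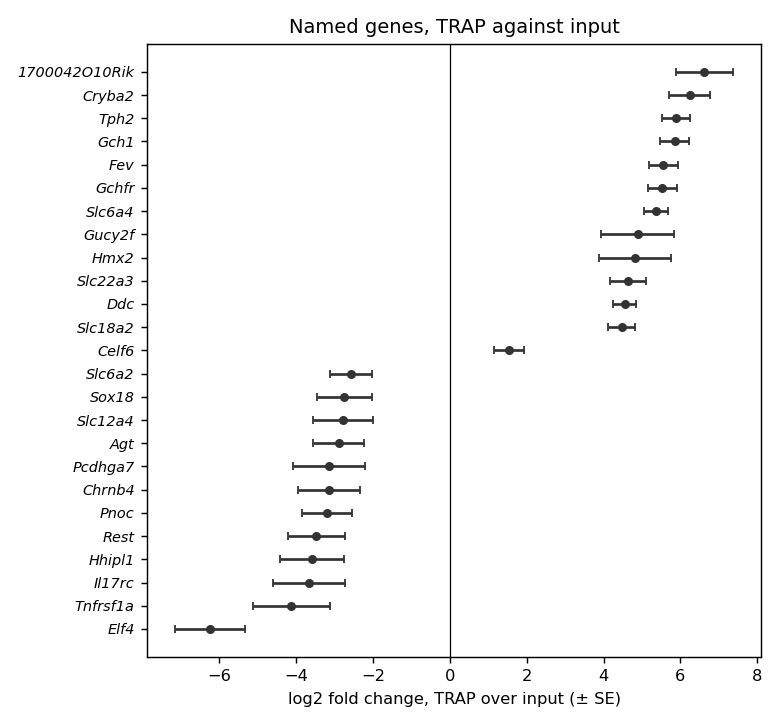
Log2 fold change ± SE of named genes between TRAP and input.

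**Figure D4:**
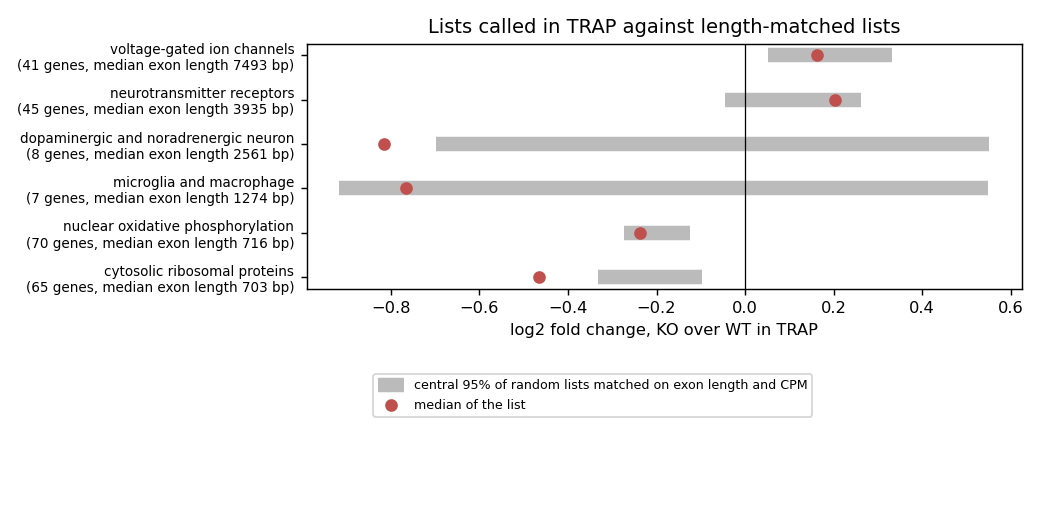
Medians of the lists called in TRAP between KO and WT, beside the central 95% of lists matched on exon length and level.

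**Figure D5:**
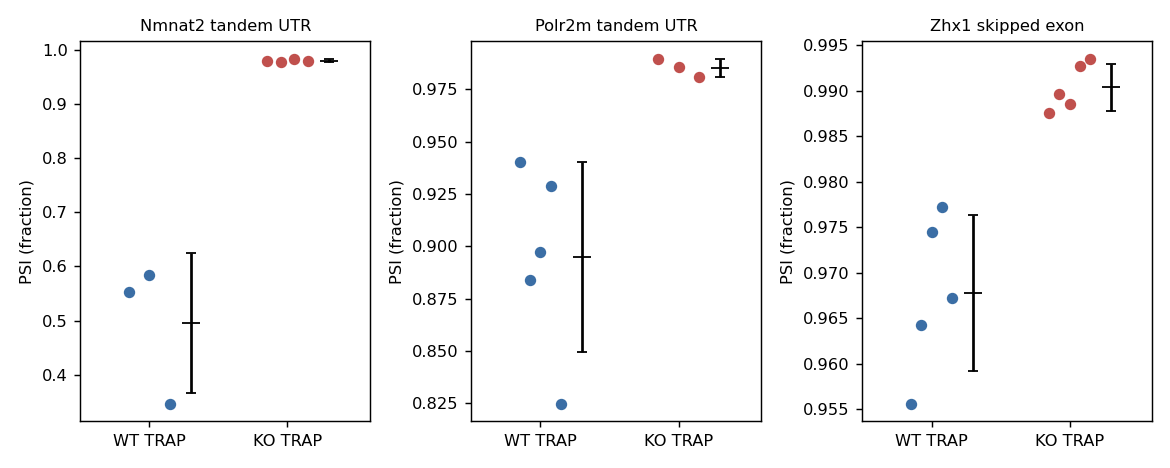
PSI of Nmnat2 and Polr2m (share of the shorter UTR per the file headers, a direction not checked) and Zhx1 (share with the exon) in each TRAP library.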

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

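The tests of WT input 2/3, the tests of sex-linked genes, the comparisons of the ribosomal and the dopaminergic list alone with length-matched lists, and the correlations of the ribosomal level were chosen after the result was seen.

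Ribosomal protein genes (median −0.47) and 3 other lists were lower, and receptor and channel genes higher, in KO than in WT TRAP, while the ribosomal list mean differed by 0.13 in run 1 and by −1.45 in run 2. In the test set before, only 2 of the 6 lists lay outside the central 95% of lists matched on exon length and level, as length predicts, and over the 10 TRAP libraries the ribosomal level fell as the slope on length (ribosomal genes left out) rose (r = −0.872, permutation p = 0.00155, adjusted p = 0.00310 over the 2 relations tried by permutation, slope and depth; rho = −0.830, permutation p = 0.00450, adjusted 0.00900; r = −0.910 without the 2 libraries farthest from the median slope, −0.845 within genotypes, −0.939 within runs). The 2 outside were the ribosomal list (−0.47 against −0.33 to −0.10) and the dopaminergic and noradrenergic list (−0.82 against −0.70 to 0.55). The matched genes were drawn independently, while genes of these 2 lists varied together between libraries (estimated correlation 0.650 and 0.211). The matched range may thus be too narrow, so length as the whole cause was not excluded and stays open for all 6 lists. For the 7 microglia genes (median −0.77, matched median −0.18) the range was wide, −0.92 to 0.55, so lying inside it says little about length. Matched medians were −0.21 for oxidative phosphorylation, 0.20 for channel and 0.11 for receptor genes. Over all genes the median was −0.20 for those up to 1762 bases and 0.23 for those from 5122 bases. The slope on length was 0.276 ± 0.570 in KO and −0.276 ± 0.420 in WT (n = 5 each, exact permutation p = 0.111). Chance was not excluded, as 34 of 100 splits of the same TRAP libraries, the real one included, gave at least its 6 lists (highest other 14, camera). Library depth stays open as well, at 5.69 ± 1.03 M counts in KO and 4.89 ± 1.24 M in WT (n = 5 each, exact permutation p = 0.333), since so few libraries do not exclude a difference. With genotype in the fit, the slope of ribosomal level on depth (0.0754 per M counts) points to more, not less, in the deeper KO. Its 95% interval (−0.40 to 0.55) spans 0, and over the 10 TRAP libraries the ribosomal level had r = −0.034 with the total count (permutation p = 0.920). An effect of genotype was not told apart from length, chance and depth.

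WT input 2 and WT input 3 had a chi-square per gene of 1.36 between them. Under the account that they come from 2 brains the value should lie with the other pairs within a group (26.2 to 95.4), and it did not. Under the account that they are 1 library under 2 labels it should not pass the highest value of 2 runs of 1 library (2.67), and it did not. Whether that library came from a KO brain was not settled: its Celf6 level of 15.7 CPM lay within those of KO input (4.90 to 22.5) and below the other WT values (34.0 and 107), and its nearest library in input was KO input 2 (chi-square per gene 21.7 to 26.8). No difference that the design names puts the same counts under 2 brains.

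Y-linked genes and Xist, which is made by the inactive X, did not match between RNA kinds of 1 number, or were seen together in 1 library. CPM of Xist and of the Y-linked genes together are given here over the total count, without TMM, unlike those of Celf6. KO TRAP 1 had 25.6 CPM of Y-linked genes beside 63.2 CPM of Xist, where the 4 other TRAP libraries with Xist had at most 0.307 and the 5 without had 55.4 to 119, though of the 4 genes taken alone only 2 lay between (Ddx3y and Eif2s3y, not Uty and Kdm5d). RNA from a male mixed into KO TRAP 1 was tested on Celf6, which was at 113 CPM there and at 21.1 to 56.3 in the other KO TRAP libraries. The direction is that of a mixture with WT RNA, so a mixture stays open. Y-linked genes in KO TRAP 1 were at 31.3% of the mean of the 5 TRAP libraries without Xist. Whether a mixture of that share would bring Celf6 to 113 CPM was not tested. WT TRAP 4 had Xist (136 CPM), WT TRAP 5 had Y-linked genes (75.3 CPM), and WT input 5 had both (Xist 36.3 CPM, Y-linked 9.73 CPM). In WT input 4 the Y-linked share was 75% of 12 reads (95% interval 42.8 to 94.5), which left a swap of numbers 4 and 5 open, and no genotype effect in the design puts Y-linked RNA beside Xist.

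Other values stood out. Ptgds in KO input 3 was at 637 CPM, against a KO mean of 202 (cause not tested). Cd68 in KO TRAP 4 was at 2.21 CPM, against a KO mean of 0.501 (cause not tested). The retained intron of Fam70a had PSI 0.00294 in WT TRAP 2, against a WT mean of 0.00816 (cause not tested). Of 75 groups tested for a value standing apart (Dixon, p below 0.05), 3 had one, where 3.75 would be expected by chance. A skipped exon of Celf6 (chromosome 9 at 59603808–59603870, mm10) had a PSI in 4 of 5 WT TRAP libraries (0.0558 ± 0.0147, n = 4) and in 0 of 5 KO TRAP libraries (Fisher exact p = 0.0476, cause not tested). Of the mutually exclusive exon events with that exon 1 had the same split and the other a PSI in 2 of 5 WT and 0 of 5 KO TRAP libraries (Fisher exact p = 0.444), while the other skipped exon of Celf6 had 0 in TRAP, and in input the exon had 0 of 5 against 0 of 3. Celf6 RNA was itself lower in KO TRAP (50.5 against 140 CPM), and a PSI was kept only where its credible interval was at most 0.20 wide. The missing values are thus no sign of an isoform change. The list medians of the interaction (−0.50, −0.28, −0.60, −1.10 and 0.37) had the direction of those in TRAP, and 16 of 60 splits, the real one included, gave at least its 5 lists (highest other 14, camera), so chance was not excluded.

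Ttr, a choroid plexus gene, was at 93.0 ± 102 CPM in KO and 725 ± 810 CPM in WT TRAP (n = 5 each; exact permutation p = 0.159), and at 955 ± 1068 CPM in KO (n = 5) and 2643 ± 1984 CPM in WT input (n = 3; exact permutation p = 0.232).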

How the results depend on the processing

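Chosen after the result was seen were the tests without KO TRAP 1 and WT input 2/3 ("doubted" below), those with WT input 2 and 3 apart or left out, and for gene lists the interaction, leaving out each library, leaving out the run, and the block in TRAP against input. The other tests were chosen before. Of 90 named results 77 kept their direction in every alternative, and of 2109 alternatives 1953 gave the same call and direction.

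Genes called between KO and WT in input were 0 with edgeR, 4 without the expression filter, 1 with a block, 89 with run 2 alone, which holds 1 WT input library, and 0 to 1 when leaving out each library (1 without KO input 3). In TRAP they were 0, with 1 by DESeq2, 16 without the filter and 264 with run 2 alone. For the interaction they were 0, with 3 by DESeq2 and 3 without the filter. TRAP against input had 673, with 1290 by DESeq2, 1065 without the filter, 413 with the brain as numbered as a block, 160 in WT alone, 124 in KO alone, and 346 to 831 when leaving out each library.

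Celf6 in TRAP was −1.50 without the filter, where it passed, and −3.23 in input with run 2 alone, which rests on 1 WT library. Celf6 in the interaction changed sign with a block (−0.23) and ranged from −1.12 to 0.94 when leaving out each library. Tph2 in input ranged from −0.21 to 0.87, and was −0.78 with WT input 4 added, −0.93 with run 2 alone and −0.15 in the doubted setting. Slc6a4 in input ranged from −0.14 to 0.49, and was −0.15 with the repeat runs in place of the originals, −0.20 with WT input 4, −0.15 with a block and −0.13 with run 1 alone. Ddc in input ranged from −0.57 to 0.64, and was 0.14 with WT input 2 and 3 apart and 0.65 with run 1 alone. Slc18a2 in input ranged from −0.0913 to 0.37, and was −0.10 with WT input 4 and −0.27 with a block. BC004004 in input was −0.0557 with WT input 4. In TRAP Tph2 was −0.14 with run 1 alone, Slc6a4 was 0.29 with run 2 alone (−0.32 to 0.10 over libraries), and Ddc 0.24 with run 2 alone (−0.25 to 0.0455). In the interaction Tph2 was −0.0644 with a block (−0.35 to 0.48), Slc6a4 0.11 with WT input 4 and 0.14 with a block, Fev ranged from −0.90 to 0.0272, and Ddc was −0.0738 without the run, −0.21 with WT input 2 and 3 apart and −0.13 with a block (−0.58 to 0.46).

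Lists called in input were 0 to 1 over libraries. In TRAP 6 lists became 0 with an estimated correlation, 0 with fry, and 1 to 7 over libraries. In the interaction 5 became 0 with an estimated correlation, 0 with fry, 3 in the doubted setting and 0 to 7 over libraries. In TRAP against input 12 became 1 with an estimated correlation.

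Splicing events called in TRAP (1) were 0 with PSI held at 0.001, 2 where a value was needed in every library, 0 with the run, 0 with a block, 0 in the doubted setting and 0 to 1 over libraries. Tandem UTR events called in TRAP (2) were 1 in the authors' deposited table, 0 where a value was needed in every library, 1 with the run, 0 with KO and WT numbers as a block (Nmnat2 and Polr2m adjusted p 0.696, Zhx1 0.401, limma), 1 in the doubted setting and 0 to 2 over libraries. In input, leaving out WT input 1, 5 or 2/3 left too few WT libraries to test any event.

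Splits of the same libraries were counted with the real grouping as 1 of them. For TRAP against input only the real grouping reached its own count, 1 of 60 for genes (673, highest other 83) and 1 of 60 for lists (12, highest other 11). For genes no other split drawn came near the real count, which argues against chance. For lists the margin was too narrow, with so few splits drawn, to exclude chance for the count. For TRAP tandem UTRs 2 of 100 reached the real 2 (highest other 2). Events with missing values can become untestable in other splits, which lowers their counts, so chance was not excluded there. It was not excluded for TRAP splicing either, where 16 of 100 reached the real 1 (highest other 3). Where the real count was 0 every split reached it, so nothing follows about chance: 55 of 55 for input genes (highest other 3) and lists (8), 100 of 100 for TRAP genes (2), 60 of 60 for interaction genes (0), and 56 of 56 for input splicing (2) and tandem UTRs (2).

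Equal numbers in KO and WT were not taken as pairs: residual levels had r of 0.071 to 0.242 in input (3 of 3 closest to their own number) and −0.129 to 0.132 in TRAP (1 of 5).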

Other observations

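The camera and Fisher tests of CELF6-bound genes below were chosen before the result was seen, and the permutation tests of them after.

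Several neuropeptide genes rose in TRAP against input, among them those of thyrotropin-releasing hormone, Trh (3.87 ± 0.61), of the granins Scg2 (1.92 ± 0.27) and Chgb (1.43 ± 0.23), and Tac1 (0.99 ± 0.27). Of the 30 neuropeptide genes 4 rose over all genes, and 5 rose and 5 fell over the list alone, but 20 of the 30 were negative (edgeR; median −0.54, camera adjusted p = 0.401). Of 48 neurotransmitter receptor genes, Adra1b (2.24 ± 0.29), Gabrg3 (2.59 ± 0.58) and Glra2 (1.12 ± 0.28) were the 3 that rose and Grin1 (−1.25 ± 0.27) the 1 that fell over all genes, with 3 and 2 over the list alone (median 0.22, camera adjusted p = 0.436). Epha3 rose (3.59 ± 0.99) and Ncam1 (−0.79 ± 0.20), Nlgn3 (−0.84 ± 0.22) and Ephb1 (−0.82 ± 0.24) fell among 54 axon guidance and adhesion genes, with 3 and 4 past over the list alone (median 0.0128, camera adjusted p = 0.479). Xbp1 rose (0.9996 ± 0.230) among 20 unfolded protein and stress response genes, with 2 over the list alone (median −0.00901, camera adjusted p = 0.645), and Oasl2 (2.91 ± 0.73) among 12 interferon and inflammation genes, also the 1 over the list alone (median −0.57, camera adjusted p = 0.401).

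Genes of splicing and release were mixed in the same comparison. Of 6 CELF family genes, Celf6 rose and Celf4 (−1.13 ± 0.21) and Celf2 fell, over all genes and over the list alone alike (median −0.21, camera adjusted p = 0.381). Of 40 neuronal RNA-binding and splicing regulators, Cpeb1 (1.31 ± 0.35) rose and Elavl3 (−2.04 ± 0.30), Rbfox1 (−1.33 ± 0.27), Nova1 (−0.99 ± 0.25) and Msi1 (−1.21 ± 0.35) fell, with 1 and 5 over the list alone (median −0.11, camera adjusted p = 0.124). Bsn (−0.82 ± 0.18) and Syt2 (−1.37 ± 0.40) were among 5 of 37 synaptic vesicle release genes that fell, with 6 higher and 9 lower over the list alone (median −0.11, camera adjusted p = 0.450). Of 41 voltage-gated ion channel genes, Scn3b (1.003 ± 0.226) rose and 5 fell, with 1 and 7 over the list alone (median −0.14, camera adjusted p = 0.196). Cholinergic neuron genes (6 tested, median −0.69, adjusted p = 0.0902), ependymal and choroid plexus genes (11 tested, median −0.59, adjusted p = 0.401), nuclear oxidative phosphorylation genes (70 tested, median −0.05, adjusted p = 0.226) and genes within 10 Mb of Celf6 (184 tested, 4 higher and 6 lower, 9 and 8 over the list alone, adjusted p = 0.866) did not pass camera either.

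Genes bound by CELF6 in CLIP (1204 of 4762 genes in the tables) were asked whether their level or isoforms differed between genotypes more than those of other genes. Their level did not. In TRAP the median of 1169 bound genes was 0.03 (camera p = 0.715), and their mean level less that of the other genes gave an exact permutation p = 1.00 (n = 5 each). In input 1170 were tested (camera p = 0.932, and an exact permutation p = 0.875 with n = 5 KO and n = 3 WT). Of events in bound genes 5.23% had an unadjusted p below 0.05 in TRAP (46 of 879), against 6.35% in other genes (84 of 1322; Fisher exact p = 0.310). In input it was 2.85% (18 of 631) against 4.71% (36 of 765; Fisher exact p = 0.0935). A small effect of binding was not excluded by these tests.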
